A study of Argyrosomus regius with 12 samples.

How the data were processed

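RNA was measured in spleens of juvenile meagre (Argyrosomus regius), a marine bony fish, in 12 libraries. Per the labels, each library was made from the pooled spleens of 4 fish with a directional kit, which keeps the strand of the RNA. The replicates are therefore pools of separate animals, and 3 pools stand for the 12 fish of each group. Each pool has 1 library, so the spread between pools holds differences between fish as well as library noise.

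The values are estimated read counts per assembled transcript, deposited as whole numbers in a single matrix of 58975 transcripts and 12 columns. The submitters' processing notes name Trimmomatic 0.39, FastQC, Bowtie2, RSEM and DESeq2, with no role or order. RSEM gives expected counts that need not be whole, so the deposited counts were treated like expected counts that the authors had already rounded. All values were whole numbers, and the library totals differed as unnormalised counts do. The transcript identifiers are of the kind the Trinity assembler writes, with a gene part and an isoform part. By the gene part the transcripts fall into 42480 Trinity genes, of which 38013 hold 1 isoform and 4467 hold several, up to 96. The assembly, its annotation and the strand setting of the counting are not given in the sources used here. Isoforms of 1 Trinity gene share sequence, and so do near-identical gene copies, so the split of reads among them is an estimate and is uncertain. The files do not pair the identifiers with gene names, and no reference was used here.

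Counts were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test with robust estimation. The model held 1 mean per group and all 12 libraries, so that the 4 groups shared 1 estimate of the spread. Libraries were scaled by TMM, with factors from 0.809 to 1.19. The edgeR expression filter kept 42308 transcripts (71.7%), and 16667 were not tested, of which 2237 had 0 counts in every library. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison, and a transcript was called at an adjusted p below 0.05. The standard error of a log2 fold change was taken from the test's F statistic. Levels are given as CPM, the usual per-library scaling of counts, here with the TMM-scaled library totals, and log2 CPM used a prior count of 2. There were 5 comparisons, namely LPS against PBS at 4 h and at 24 h, 24 h against 4 h within PBS and within LPS, and the difference between the LPS effects at 24 h and 4 h.

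Total counts ran from 29614365 to 56556752 per library. Where a group had 0 counts in all of its pools, a fold change was given as a lower bound against a floor of 3 counts in each library. With 1 to 3 counts in a group, the ratio of summed, library-scaled counts was given with an exact 95% binomial interval. Such intervals and floors cover counting error at most, because they leave out the spread between pools. Sequenced fragments without molecular identifiers are not independent molecules, so counting error may not be fully covered either.

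The fit was tested on simulated counts for the 42308 transcripts, with 200 of them changed by known factors. The 200 were drawn from transcripts with a mean log2 CPM above 1, so recovery at lower levels was not tested. In the 24 h comparison it recovered 0 of 67 transcripts changed 2-fold, 28 of 67 (41.8%) changed 4-fold and 46 of 66 (69.7%) changed 8-fold, and it called 1 unchanged transcript. In the 4 h comparison the recovered numbers were 0 of 67, 27 of 67 (40.3%) and 45 of 66 (68.2%), with 2 unchanged transcripts called. Simulated changes of 2-fold were thus not recovered at the spread of these pools with 200 transcripts changed. So few changed transcripts also make the adjusted threshold strict, so the spread alone is not shown to be the reason. In the measured 24 h comparison, 608 of the 749 calls had a fitted change of at least 2-fold, and the others were smaller. All 66 pairs of libraries were compared by a chi-square test of their counts. The chi-square per degree of freedom was at least 36.5 for every pair (lowest for LPS 4 h replicate 2 with LPS 24 h replicate 1), and between 51.7 and 174.5 within groups, so no library was counted as a repeat of another.

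The groups, the tests, the rule for named transcripts and most alternatives were chosen before the data were examined. The alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), median-ratio and upper-quartile scaling, no expression filter, a filter of CPM above 1 in 3 samples, a fold threshold of 2, an adjusted p below 0.01, the replicate number as a block, a fit of the compared groups alone and each replicate left out in turn. Counts summed over the isoforms of each Trinity gene, with and without LPS 4 h replicate 2, were added after seeing the data, as was leaving a pool out of comparisons between other groups, where it enters only through the shared spread, scaling and filter. The rule named the 2 transcripts with the largest rise and the 2 with the largest fall per treatment comparison, among those called, with a mean log2 CPM above 1 and with LPS and PBS pools that did not overlap. No transcript met it at 4 h and 712 met it at 24 h. A set of 25 lists of immune pathways, spleen cell types and neighbouring tissues had been fixed by gene name. They were not tested, because the identifiers carry no names.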

Results

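The data describe the early transcriptional response of the meagre spleen, a main immune organ of bony fish, to a bacterial cell wall component. Juveniles of 22 g kept at 22 °C received an injection into the body cavity. The treated fish received lipopolysaccharide (LPS) at 10 µg per g of body weight, purified from the fish pathogen Photobacterium damselae subsp. piscicida. Control fish received phosphate-buffered saline (PBS). Spleens were taken at 4 h and at 24 h, which gave 4 groups of 3 pools. The PBS 4 h pools had 29614365, 35853457 and 33024984 counts for replicates 1 to 3, and the PBS 24 h pools 32820406, 33519016 and 38888446. The LPS 4 h pools had 40319889, 32821943 and 36396959 counts, and the LPS 24 h pools 34386669, 37133770 and 56556752. Between 81.4% and 86.0% of the 58975 assembled transcripts were detected in each library.

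LPS 4 h replicates 1 and 3 stood far from the other 10 libraries. On the first principal component of log2 CPM, which held 21.9% of the variance, they lay at 192.5 and 218.0. LPS 4 h replicate 2 lay at -29.5, among the libraries of the other groups, which ran from -77.8 to -1.24. Its mean correlation across transcripts was 0.895 with the PBS 4 h pools and 0.897 with the LPS 24 h pools, against 0.853 with the LPS 4 h replicates 1 and 3. By the chi-square test of counts, its nearest library was LPS 24 h replicate 1 (36.5 per degree of freedom, the lowest of all 66 pairs), followed by PBS 4 h replicate 1 (42.9). By Pearson's r across transcripts its nearest was PBS 4 h replicate 3 (0.901), with PBS 24 h replicate 2 and LPS 24 h replicate 1 next (both 0.899). Transcripts are not independent replicates, so these correlations describe the libraries only. The label of the pool was kept in every comparison.

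**Figure D1:**
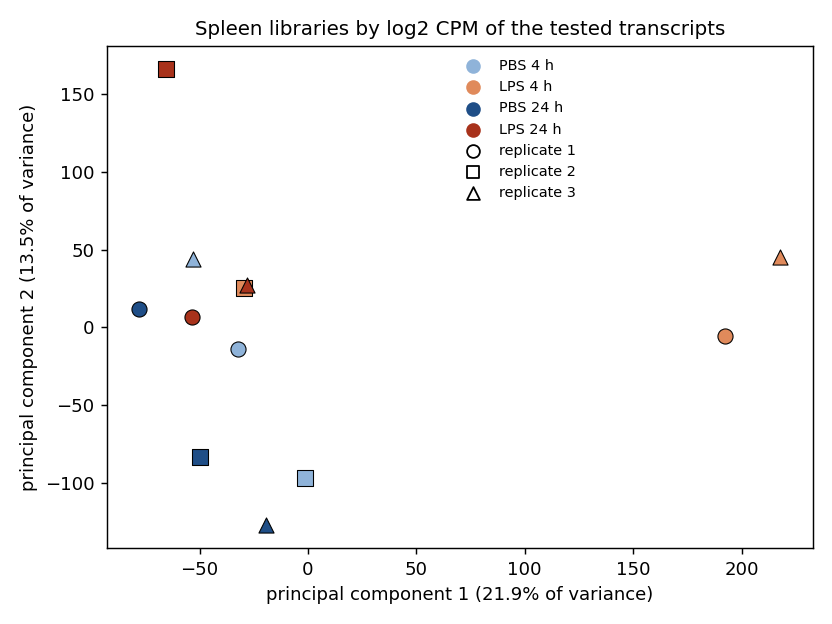
Each point is 1 of the 12 libraries, placed by the first 2 principal components of log2 CPM over the tested transcripts, with colour for the group and marker shape for the replicate number. LPS 4 h replicates 1 and 3 lie at 192.5 and 218.0 on the horizontal axis, and LPS 4 h replicate 2 lies at -29.5 among the other groups.

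The first comparison asked which spleen transcripts LPS had altered at 4 h. LPS 4 h replicates 1 and 3 shared a broad rise of transcripts that replicate 2 did not show, and a fall that by the median it showed at most in small part. With all 3 LPS pools, edgeR called 0 of 42308 transcripts, and the lowest Benjamini-Hochberg adjusted p was 0.173. An unadjusted p below 0.05 was reached by 6676 transcripts (15.8%), where 2115 would be expected by chance, and 4005 of these were higher and 2671 lower in LPS pools. DESeq2 called 2565 transcripts, 1840 of them higher in LPS pools, and limma-voom called 0. LPS and PBS pools did not overlap for 17.1% of transcripts, against 10% expected by chance for 3 against 3.

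The count at 4 h rested on a single pool. Without LPS 4 h replicate 2, edgeR called 6391 of 44153 transcripts, 3114 higher and 3277 lower in the 2 remaining LPS pools. Leaving out any other LPS 4 h or PBS 4 h pool gave 0 calls. The median log2 fold change was 1.55 for the transcripts higher in LPS and -1.49 for those lower. With transcripts at 0 counts in 1 group set to their bound, the medians were 1.55 and -1.48. Across 650 transcripts called at least 4-fold higher in that fit, with a mean log2 CPM above 1, replicate 2 reached a median of 0.00223 of the rise in CPM seen in replicates 1 and 3, with quartiles of -0.0284 and 0.0488. Across 529 transcripts called at least 4-fold lower, it reached a median of 0.162 of the fall, with quartiles of -0.0252 and 0.326. These transcripts were chosen against the same PBS 4 h pools that serve as the baseline, which can by itself give such a share. No other library was scored in this way, so a partial fall in replicate 2 is not shown.

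At 24 h most of the transcripts called by edgeR were higher under LPS. Of 42308 transcripts, 749 were called by edgeR, 709 of them (94.7%) higher and 40 lower in LPS 24 h than in PBS 24 h pools, and these came from 727 Trinity genes. The transcripts that rose had a median log2 fold change of 1.40, with quartiles of 1.08 and 1.92, and those that fell had a median of -1.28. Medians were the same with the 9 higher and 3 lower transcripts at 0 counts in a whole group set to their bound. At the same bounds, at least a 2-fold change was seen in 577 of the transcripts that rose and 31 of those that fell, and at least a 4-fold change in 154 and 10. The called transcripts were well expressed, with a median log2 CPM of 4.40. In all 749 the 3 LPS pools lay outside the range of the 3 PBS pools, which was so for 23.5% of all tested transcripts against 10% expected by chance.

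The calls at 24 h were close to the threshold. The lowest Benjamini-Hochberg adjusted p from edgeR was 0.0112, and an adjusted p below 0.01 was reached by 0 transcripts. The lean towards higher levels was weaker in wider sets of transcripts and among DESeq2 calls. Over all tested transcripts the median log2 fold change was -0.0728. Of 6574 transcripts with an unadjusted p below 0.05, 3803 were higher and 2771 lower, of all tested transcripts whose pools did not overlap 5544 were higher and 4392 lower, and of 3160 called by DESeq2 2447 were higher and 713 lower. With limma-voom, 781 were called, 736 higher and 45 lower. With the 24 h groups alone in the fit, the count was 215. Without PBS 24 h replicates 1, 2 and 3 in turn the counts were 122, 0 and 17, and without LPS 24 h replicates 1, 2 and 3 they were 1022, 41 and 0. Pools of the other time point enter through the shared spread, scaling and filter, and without PBS 4 h replicates 1, 2 and 3 the counts were 352, 372 and 306. Without LPS 4 h replicate 2 the count was 1435, which included all 749.

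As a set, the transcripts called higher at 24 h had a lower mean in PBS 24 h than in PBS 4 h pools. Relative to the mean of the PBS 4 h pools, the 709 transcripts that rose averaged 1.00 ± 0.28 log2 CPM in LPS 24 h pools (SD, n = 3) and -0.64 ± 0.09 in PBS 24 h pools (SD, n = 3). The LPS 4 h pools averaged 0.24 ± 0.08 (SD, n = 3), and replicate 2, at 0.29, lay beside replicates 1 and 3 at 0.15 and 0.28. The LPS 4 h pools entered the choice through the shared spread, which favours transcripts on which they are alike. The 40 transcripts that fell averaged -1.46 ± 0.17 in LPS 24 h pools, 0.30 ± 0.14 in PBS 24 h pools and -0.31 ± 0.08 in LPS 4 h pools (SD, n = 3 each). The values of the 24 h pools are pushed apart by the choice of transcripts on these same pools. Over 500 transcripts chosen as higher at 24 h without the pool scored, LPS 24 h pools averaged 0.88 ± 0.24 and PBS 24 h pools -0.55 ± 0.15 (SD, n = 3 each), and transcripts that fell were not examined in this way.

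**Figure D2:**
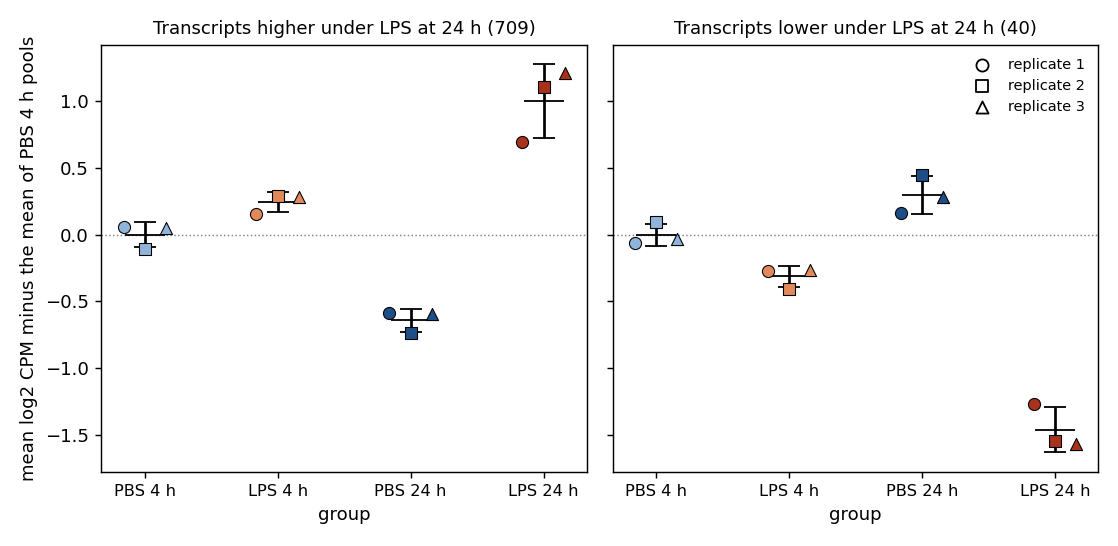
Points show, for each library, the mean log2 CPM of the transcripts called higher (left, 709) or lower (right, 40) at 24 h, minus the mean of the PBS 4 h pools, with marker shape for the replicate number. Horizontal bars and whiskers give the mean ± SD of the 3 pools of a group, and the PBS 24 h pools lie at -0.64 on the left while the LPS 24 h pools lie at 1.00.

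The rule for named transcripts gave 4 identifiers at 24 h, and the files do not pair them with gene names. TRINITY_DN5655_c2_g1_i4 was at 5.71 ± 1.55 CPM in LPS 24 h pools (SD, n = 3) and had 0 counts in all PBS 24 h pools, so it was at least 67.7-fold higher against a floor of 3 counts in each library (edgeR Benjamini-Hochberg adjusted p = 0.0225). It was at 14.2 ± 11.6 CPM in LPS 4 h pools and 1.02 ± 0.32 in PBS 4 h pools (SD, n = 3 each), with 1.15 CPM in LPS 4 h replicate 2 and 18.2 and 23.3 in replicates 1 and 3. TRINITY_DN354_c0_g1_i1 was at 50.8 ± 19.9 CPM in LPS 24 h pools and 0.032 ± 0.055 in PBS 24 h pools (SD, n = 3 each). The PBS 24 h pools held 3 counts of it in all, which gave a ratio of 1800 with a 95% counting interval from 616 to 8731 (edgeR Benjamini-Hochberg adjusted p = 0.0325). At 4 h it varied between control pools, with 0 counts in PBS 4 h replicate 3 and 487 in replicate 1.

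TRINITY_DN22_c0_g1_i21 fell from 7.58 ± 0.51 CPM in PBS 24 h pools to 0.045 ± 0.044 in LPS 24 h pools (SD, n = 3 each). Its log2 fold change was -7.28 with a standard error of 0.82 (edgeR Benjamini-Hochberg adjusted p = 0.0125), and at 4 h its means were 3.22 CPM under LPS and 3.61 under PBS. TRINITY_DN4422_c0_g1_i4 fell from 3.81 ± 1.84 CPM in PBS 24 h pools to 0.439 ± 0.108 in LPS 24 h pools (SD, n = 3 each). Its log2 fold change was -3.10 with a standard error of 0.58 (edgeR Benjamini-Hochberg adjusted p = 0.0299).

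Each of these 4 transcripts is 1 of several isoforms of its Trinity gene, and the summed counts changed much less on the log2 scale. In CPM, the other isoforms of TRINITY_DN5655_c2_g1_i4 rose by 7.83 beside its 5.71. Those of TRINITY_DN354_c0_g1_i1 rose by 89.8 beside its 50.8. The other isoforms of TRINITY_DN22_c0_g1_i21 rose by 13.5 while it fell by 7.54, and TRINITY_DN4422_c0_g1_i4 was not examined in this way. The Trinity gene of TRINITY_DN5655_c2_g1_i4, with 4 isoforms, had a log2 fold change of 0.55 (edgeR Benjamini-Hochberg adjusted p = 0.139), and of 0.55 without LPS 4 h replicate 2, where it was called (edgeR Benjamini-Hochberg adjusted p = 0.0477). The sum for TRINITY_DN354_c0_g1_i1, over 8 isoforms, rose by 1.41 (edgeR Benjamini-Hochberg adjusted p = 0.0124). For TRINITY_DN22_c0_g1_i21 the sum over 34 isoforms lay in the opposite direction, at 0.11 (edgeR Benjamini-Hochberg adjusted p = 0.762). The sum over 4 isoforms for TRINITY_DN4422_c0_g1_i4 was at -0.93 (edgeR Benjamini-Hochberg adjusted p = 0.140).

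The 4 named calls did not all hold with a pool left out. The call of TRINITY_DN5655_c2_g1_i4 ended without any 1 of the PBS 24 h pools or without LPS 24 h replicate 2 or 3, at edgeR Benjamini-Hochberg adjusted p from 0.0666 to 0.113. The call of TRINITY_DN354_c0_g1_i1 ended without the same 5 pools, at 0.0914 to 0.165 by the same test and adjustment. For TRINITY_DN22_c0_g1_i21 the call ended without PBS 24 h replicate 2 (0.0993) or LPS 24 h replicate 3 (0.0609). That of TRINITY_DN4422_c0_g1_i4 ended without any 24 h pool except PBS 24 h replicate 1, at 0.0662 to 0.130, and with the 24 h groups alone in the fit (0.0566). With limma-voom, the Benjamini-Hochberg adjusted p of the 4 transcripts was 0.450, 0.588, 0.0641 and 0.0825, in the order named.

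**Figure D3:**
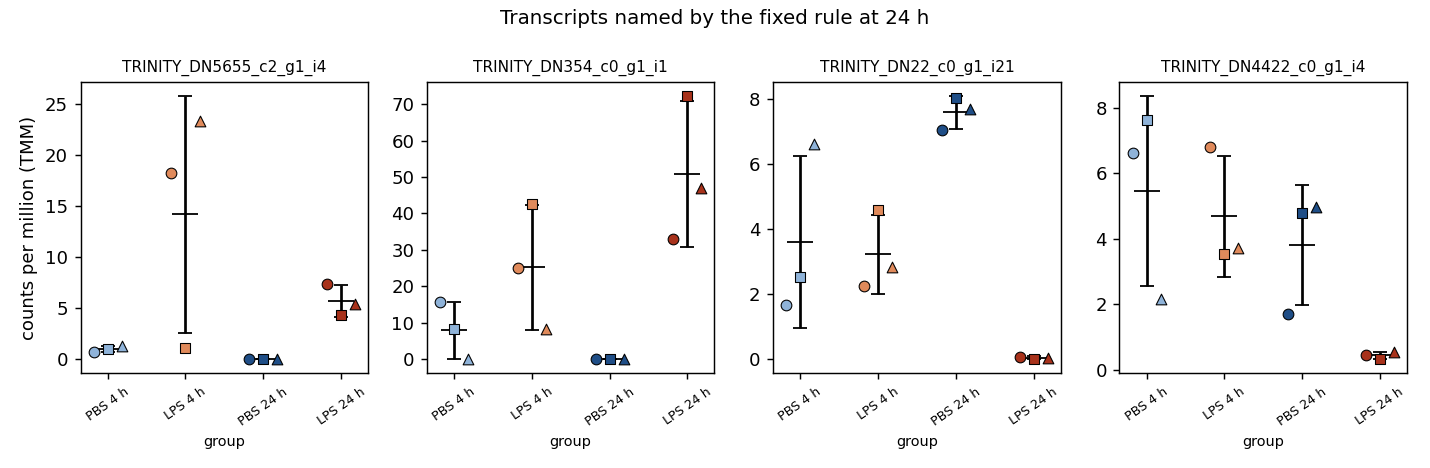
Each panel shows 1 named transcript, with its level in CPM (linear axis) in each library, marker shape for the replicate number (circle 1, square 2, triangle 3) and bars with whiskers for the mean ± SD of 3 pools. In the left 2 panels the PBS 24 h pools lie at or near 0, and in the right 2 panels the LPS 24 h pools lie lowest, at means of 0.045 and 0.439.

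The change between 4 h and 24 h in PBS fish gives the background of time after injection. No transcript was called in it by edgeR (0 of 42308, lowest Benjamini-Hochberg adjusted p 0.0913). An unadjusted p below 0.05 was reached by 2355 transcripts (5.57%), of which 740 were higher and 1615 lower at 24 h, against 2115 expected by chance. DESeq2 called 503 transcripts and limma-voom 0. Without LPS 4 h replicate 2, which belongs to neither group and enters through the shared spread, scaling and filter, edgeR called 83 of 44153 transcripts, 82 of them lower at 24 h.

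In LPS fish, 9848 transcripts (23.3%) had an unadjusted p below 0.05 between 4 h and 24 h, 4612 higher and 5236 lower at 24 h. None of the 42308 was called by edgeR (0 calls, lowest Benjamini-Hochberg adjusted p 0.0683), while DESeq2 called 6035 and limma-voom 0. With all 12 libraries and counts summed per Trinity gene, a setting added after seeing the data, edgeR called 2534 Trinity genes. Without LPS 4 h replicate 2, edgeR called 8999 transcripts, 4920 higher and 4079 lower at 24 h. Without LPS 24 h replicate 2 it called 1, and without any 1 of the other LPS pools 0.

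Whether the effect of LPS differed between 4 h and 24 h was tested directly. By edgeR 0 of 42308 transcripts were called (lowest Benjamini-Hochberg adjusted p 0.0574), with 5877 (13.9%) at an unadjusted p below 0.05. DESeq2 called 1409 and limma-voom 0. Without LPS 4 h replicate 2, 4202 transcripts were called, 2654 with a more positive and 1548 with a more negative LPS effect at 24 h, and without LPS 24 h replicates 1 and 2 the counts were 3 and 1. In the fit without LPS 4 h replicate 2, the 3114 transcripts higher at 4 h had a median log2 fold change of 0.21 at 24 h, and the difference was called for 1354 of them (43.5%). The 3277 lower at 4 h had a median of -0.05 at 24 h, and the difference was called for 1762 (53.8%). Over all 44153 transcripts tested in that fit the difference was called for 9.52%. These sets were chosen on the 4 h estimate that also enters the difference, which by itself raises these shares and the size of the 4 h medians.

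Across all 42308 transcripts the LPS log2 fold changes at 4 h and 24 h showed no clear correlation, with Pearson's r of -0.000756 (jackknife standard error over the 12 libraries 0.071) and Spearman's rho of 0.0521. Noise in the fold changes lowers r, so a value near 0 does not show that the effects are unrelated. Transcripts are not independent replicates, so no p is given, and the comparisons at the 2 time points share no control library. The sign was the same at both times for 52.7% of transcripts. Of the 709 transcripts that rose at 24 h, 498 (70.2%) had a positive fold change at 4 h, and of the 40 that fell, 28 (70%) had a negative one. Among the 749 called transcripts r was 0.271.

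Without LPS 4 h replicate 2, the calls at both times overlapped more in the same direction than independent lists would. Of 3114 transcripts higher at 4 h and 1328 higher at 24 h, 290 were shared, against 93.7 expected for independent lists. Of 3277 lower at 4 h and 107 lower at 24 h, 24 were shared against 7.94 expected. Opposite directions gave 99 lower then higher, against 98.6 expected, and 4 higher then lower, against 7.55. Both lists came from the same fit and its shared spread, so independent lists are only a rough reference.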

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

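Summing counts per Trinity gene, and leaving pools out of comparisons between other groups, were chosen after seeing the data. At 24 h, 749 transcripts were called, and limma-voom, both other scalings, no filter, CPM above 1 in 3 samples, a 2-fold threshold and Trinity-gene sums gave 550 to 1059. DESeq2 called 3160, the fit of the 24 h groups alone 215, an adjusted p below 0.01 gave 0, and Trinity-gene sums without LPS 4 h replicate 2 gave 2059. With each pool left out, the range was 0 to 1435. The other 4 comparisons gave 0 calls with edgeR as planned, with limma-voom and under both scalings, both filters and both thresholds. By DESeq2 they gave 2565 (LPS at 4 h), 503 (time in PBS), 6035 (time in LPS) and 1409 (difference of LPS effects). Trinity-gene sums gave 1, 5, 2534 and 5 in that order, and without LPS 4 h replicate 2 they gave 7454, 149, 10113 and 5432. Leaving out 1 pool gave ranges of 0 to 6391, 0 to 83, 0 to 8999 and 0 to 4202, with the highest value in each always without LPS 4 h replicate 2. The correlation of fold changes was 0.271 over called transcripts and between -0.0379 and 0.0375 in all other settings. TRINITY_DN22_c0_g1_i21 was the only named transcript to change direction, from -7.28 to 0.107 for its Trinity gene, and 0.109 without LPS 4 h replicate 2. The causes of these shifts were not tested.

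With the replicate number as a block (replicate block), 63 transcripts were called at 24 h, and no call was gained in the other comparisons. It ended the calls of TRINITY_DN5655_c2_g1_i4, TRINITY_DN354_c0_g1_i1 and TRINITY_DN4422_c0_g1_i4 (edgeR Benjamini-Hochberg adjusted p 0.0675, 0.0695 and 0.0956), and TRINITY_DN22_c0_g1_i21 was at 0.0473. Deviations of same-numbered pools correlated between -0.259 and 0.0873, and those of differently numbered pools between -0.168 and 0.215. Same-numbered pools were thus not more alike, and the labels state no link between them. With 3 pools per group these values cannot exclude such a link. Sums by gene name and all alternatives for the fixed gene lists were not run, because no gene names are paired with the identifiers. The transcripts called at 24 h were well covered, with a median log2 CPM of 4.40. In the simulation at 24 h, the changed transcripts all had a mean log2 CPM above 1. Recovery among them was 0 of 67 for 2-fold and 46 of 66 for 8-fold changes.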

Other observations

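The tests of LPS 4 h replicate 2 and the test of transcripts changed at least 16-fold were chosen after the result was seen. The other tests were chosen before their results were seen.

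Transcripts from Trinity genes with several isoforms were noisier than those that are the only isoform. At a mean log2 CPM between 2 and 4, the median biological coefficient of variation was 0.391 for 3028 transcripts of genes with several isoforms and 0.294 for 7062 single isoforms, and 13.6% against 0.496% had 0 counts in at least 1 library. Between 4 and 6 the medians were 0.277 and 0.244, and the shares with a 0 were 4.58% and 0.264%.

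The first pattern is the position of LPS 4 h replicate 2 apart from LPS 4 h replicates 1 and 3. The tables argue against a swap of a pool that responded like replicates 1 and 3 with another library of the series. No library of another group lay beside them (highest coordinate on the unit-length first component -0.00381). A swap of a pool that had not responded cannot be seen in this way. The rise argues against a partial mixture with 0.25 or more of such responding RNA, since replicate 2 reached a median of 0.00223 of it (upper quartile 0.0488). The fall alone does not decide this, with a median of 0.162 and an upper quartile of 0.326, which the choice of transcripts against the same PBS 4 h pools can raise. An LPS 24 h pool under a 4 h label cannot be told apart. On 500 transcripts chosen as higher at 24 h without the 24 h pool scored, replicate 2 lay at 0.28 from the PBS 4 h mean. The lowest held-out LPS 24 h pool lay at 0.61 (SD 0.24 among those pools). Replicate 2 and the PBS 4 h pools were not held out, and entered this choice through the shared spread, scaling and filter. Over the 40 transcripts called lower at 24 h, replicate 2 lay at -0.40. The LPS 24 h pools lay between -1.57 and -1.27 there, but that choice used these same pools. Replicate 2 was nearest to LPS 24 h replicate 1 by chi-square and to PBS 4 h replicate 3 by correlation (0.901), so these values point both ways. On the 500 transcripts replicate 2 lay 0.21 above the highest PBS 4 h pool, near replicates 1 (0.15) and 3 (0.29). This nearness cannot decide against a control pool under its label, because the shared spread favours transcripts on which the LPS 4 h pools are alike. The gap of 0.33 to the lowest held-out LPS 24 h pool leans against a 24 h pool. Both explanations stay open, because a single pool lies beyond 3 others on a given side in 25% of cases by chance. Fish that had not responded by 4 h, or had received less LPS, may be a biological explanation, which was not tested.

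The second pattern is that transcripts higher under LPS at 24 h were also lower in PBS 24 h than in PBS 4 h pools. Selection of transcripts low by chance in the PBS 24 h pools is argued against, since PBS 24 h pools held out of the choice still averaged -0.55 (SD 0.15) from the PBS 4 h mean, each of the 3 between -0.72 and -0.45 and below the lowest PBS 4 h pool at -0.10. Scaling is argued against too, since the difference was -0.65 with median-ratio and -0.62 with upper-quartile factors. A change in control fish with time after injection could account for it, as could a batch that follows the group, which the labels do not give, and 1 set of pools per time cannot separate them. As a hypothesis, part of the LPS effect at 24 h may be a level kept up from 4 h while it falls in controls, although between the PBS groups edgeR and limma-voom called 0 transcripts (2355 at an unadjusted p below 0.05) and DESeq2 503.

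The third pattern is that large isoform changes shrank on the log2 scale when isoforms were summed. For the 174 calls at 24 h in Trinity genes with several isoforms, the sum changed by a median of 0.861 of the transcript's own log2 change, which argues against reads moved between isoforms for most of them. Of the 34 calls with a fitted change of at least 16-fold, 21 lay in such genes, 12 of these with 0 counts in 1 group, and there the median was 0.133. These 21 transcripts held a median of 9.02% of their gene's counts, against 71.8% for the calls under 16-fold in such genes. Larger counts of the other isoforms can by themselves make the log2 change of the sum small. For these 21, the other isoforms of the gene moved the opposite way in 6. Their opposite change in CPM was a median of -1.37 times the transcript's (quartiles -5.43 and 0.759), with a median standard error of 1.53. For this part reads moved between isoforms cannot be told apart from a change of the isoform itself, because the members go both ways and the errors are large. Isoform choice by the cell, and variants that differ between pooled fish, stay open and were not tested.

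Other splits of the 6 libraries into 3 and 3 are too few for a share below 0.05, since 10 exist and the share is never under 0.1. For LPS at 24 h, 1 of the 10 splits, the real one, gave as many calls (749), and the highest other gave 4. For LPS at 4 h, time in PBS and time in LPS the real count was 0, which all 10 splits reach by construction, so these splits say nothing about chance, and the highest others were 0, 3 and 2. The same holds for the difference between LPS effects, where the real count of 0 is reached by all 100 drawn splits. There the highest other gave 593 calls, in a split that set LPS 4 h replicate 2 with PBS 4 h replicates 1 and 3, which points to a structure of the samples. For the correlation of fold changes, the real absolute r of 0.000756 is so close to 0 that all 100 drawn splits reached it (highest other 0.265), and no relation beyond chance is claimed.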
